A study of Mus musculus with 15 samples.

How the data were processed

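RNA was measured on 15 Affymetrix mouse arrays, each carrying one sample of bone marrow cells sorted by flow cytometry from C57Bl/6 mice. Per the labels, 3 arrays held old haematopoietic stem cells (HSC), 5 young HSC, 3 old granulocyte/macrophage progenitors (GMP) and 4 young GMP. Young mice were 6 to 12 weeks old and old mice 22 to 30 months old, and every sample was labelled male. HSC were gated as lineage-negative, c-Kit- and Sca-1-positive cells without Flk2 or CD48 and with CD150, and GMP as lineage-negative, c-Kit-positive, Sca-1-negative cells with CD34 and Fc gamma receptor. The protocol field describes a repeated sort, amplification of the small RNA amounts with a NuGEN whole-transcript kit, and biotin labelling. The labels do not say whether an array came from 1 mouse or from a pool, nor on which day it was processed, so p-values measure only the spread between arrays.

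The deposited table held log2 expression values for 23309 probe sets on the 15 arrays, with 0 missing values. The submitters' processing notes name RMA, affy and limma without versions, and the scale was read from the values themselves, which ran as RMA log2 values do. The medians of the arrays were close, but their interquartile ranges ran from 1.96 log2 (old HSC replicate 2) to 2.69 (young HSC replicate 1). Neither a filter on probe sets nor a genome build was stated. All 15 columns were matched to samples, and 0 columns were left over. The precision of every value was limited by the number of arrays.

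A gene was a probe set annotated with a single symbol. Of the probe sets, 20728 had 1 symbol, 1174 had several and 1407 had no annotation, and the latter groups were left out. The Entrez identifiers of 20685 of the single-symbol probe sets were found in the mouse gene table, and 0 symbols changed through it. For the 804 genes with more than 1 probe set, the brightest over the 15 arrays was used, which left 19296 genes. Of the 151 such genes called with age in HSC, 32 had another probe set with the opposite sign, and 7 genes had probe sets called in opposite directions.

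Genes were tested in R 4.3.3 with limma 3.58.1. A linear model with a mean per group was fitted to all 15 arrays, with empirical Bayes moderation at default settings. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 on the adjusted p. Differences were coded as old minus young within each cell type, as HSC minus GMP within each age, and as the age difference in HSC minus that in GMP. Tested on simulated data with 19296 genes and the group sizes of each comparison, changes of 1 log2 were recovered for 92% of genes for age in HSC, 90% for age in GMP, 63% for the difference between both age effects, 97% for HSC against GMP in young mice and 89% for HSC against GMP in old mice, and changes of 0.5 log2 for 36% of genes for age in HSC, 23% for age in GMP, 0% for the difference between both age effects, 41% for HSC against GMP in young mice and 14% for HSC against GMP in old mice. False calls made up from 0% (HSC against GMP in old mice) to 7.25% (age in HSC) of the simulated calls. A list of genes lowered by 0.3 log2 in simulated old HSC was called in 20 of 20 runs. The simulated genes varied independently of each other, and no simulated arrays shared a difference across genes. These runs therefore do not show how the gene test or the list test behaves where genes are correlated. The recovery and false call rates need not hold for the real arrays.

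Gene lists were tested with camera, with a preset correlation of 0.01 between genes, over 31 lists and with Benjamini-Hochberg adjustment over the lists. Each was also tested with a correlation estimated per list, and with fry, which asks whether the genes of a list move one way on balance. For age in HSC the median of each list was also set against 10000 random lists matched on mean expression. Their genes were drawn singly, so these lists do not carry the correlation between genes of a real list. The lists covered origin licensing, the replication fork, the ATR checkpoint, homologous recombination, end joining, p53 targets, mitosis, G1 regulators, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, glycolysis, autophagy, antioxidants and chromatin modifiers. They also covered genes that the literature reports as higher in old HSC, HSC identity, megakaryocyte, lymphoid, granulocyte, interferon, NF-kB, immediate early and unfolded protein response genes, and markers of 7 other cell types. Sort markers and sex-linked genes were given gene by gene. List genes missing from the table were not analysed here.

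The genes named were chosen by rule. For the age comparisons they were the 8 largest changes in each direction among called genes whose groups did not overlap, and for the other comparisons the 6 largest. For each list described they were up to 4 called members by size, or up to 2 where none was called. Mcm2 to Mcm7, the sort markers, the sex-linked genes and Cdkn2a were always included where measured. The rule also listed Cdkn1a, for which no value is given here. Named genes outside the rule are said to be so.

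The lists, tests, naming rule and most alternatives were fixed before the data were examined. These alternatives were quantile normalization, subtraction of each array's median, removal of the dimmest 40% of genes, the mean of a gene's probe sets, a trended and robust variance prior, array weights, a fit of only the groups compared, replicate numbers as a block, and leaving out each array. Added after the data were examined were the interquartile range or the Xist level of each array as a covariate, and fits without the replicate 4 arrays of both young groups, with and without old HSC replicate 2. Whether replicate numbers pair samples was checked by correlating, across genes, the deviations of same-numbered arrays from their group means. For young HSC and young GMP these correlations were 0.287, 0.235, 0.161 and 0.525 for numbers 1 to 4, all over the limit of 0.1, so the numbers were taken to pair those arrays. The highest correlations with another number were 0.104, 0.247, 0.139 and -0.168. The limit was thus also passed by other numbers for 1 to 3, and only number 4 stood clearly apart. The pairing rests on the values, since the labels give only the numbers. For old HSC and old GMP, number 1 reached 0.05, and these arrays were taken to share only a number. A sample far from its group was sought with Dixon's ratio in the groups of 4 and 5 arrays. A permuted grouping of the arrays was counted once for each split into groups of the same sizes, with 100 drawn where there were more.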

Results

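Gene expression was measured in 2 populations of blood-forming bone marrow cells from young and old C57Bl/6 mice: HSC, the stem cells, and GMP, progenitors of granulocytes and macrophages. The 15 arrays comprised 3 of old HSC, 5 of young HSC, 3 of old GMP and 4 of young GMP. The series title names replication stress in ageing stem cells as its subject. Cell type was the largest difference among the arrays, with 57.8% of the variance on the first principal component. The second component held 19.1%. On it 5 of the 6 old arrays lay between 8.25 and 42.5, young HSC replicate 4 at 19.1 and young GMP replicate 4 at 20.5, while old GMP replicate 3 lay at -6.16 and the other young arrays between -29.4 and -7.05. The spread of values within an array, its interquartile range, was 2.15 ± 0.19 log2 in old HSC (SD, n = 3), 2.51 ± 0.19 in young HSC (n = 5), 2.34 ± 0.12 in old GMP (n = 3) and 2.42 ± 0.20 in young GMP (n = 4). The replicate 4 arrays had the narrowest spread of their groups, 2.21 in young HSC and 2.13 in young GMP.

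Sex-linked genes differed between young arrays although every sample was labelled male. Xist, the RNA that coats the inactive X chromosome of females, lay between 5.46 and 5.84 log2 on the 6 old arrays. On 7 of the 9 young arrays it was more than 1 log2 above the highest old array, up to 11.51 on young HSC replicate 4, and it was 4.72 on young HSC replicate 1 and 5.49 on young GMP replicate 1. The mean of the Y-linked genes Kdm5d, Eif2s3y and Uty was 4.94 on young HSC replicate 4 and 5.20 on young GMP replicate 4, against 8.80 on young HSC replicate 1 and 8.61 on young GMP replicate 1. On the old HSC arrays Xist lay below the arrays' lower quartile of 6.25 to 6.43, so that no fold is given. It was called lower in old than in young HSC (limma adjusted p = 0.0368), a call that held without young HSC replicate 1 or 4 but not without any 1 of the other 6 HSC arrays. The log2 difference of -3.96 ± 1.18 (SE) is not an exact size, for the same reason of low signal.

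**Figure D1:**
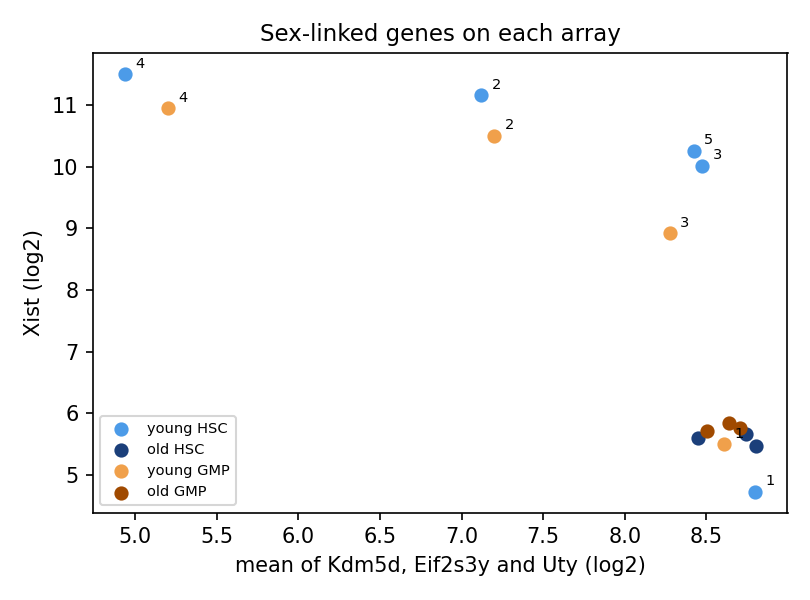
Xist (log2, vertical axis) against the mean of Kdm5d, Eif2s3y and Uty (log2, horizontal axis), 1 point per array, coloured by group and numbered by replicate for the young groups. The 6 old arrays lie together with Xist between 5.46 and 5.84, and 7 of the 9 young arrays lie more than 1 log2 above them.

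The first comparison asked which genes differ between old and young HSC. Of DNA replication genes, all of Mcm2 to Mcm7, subunits of the helicase that opens replication origins, fell in old HSC, from 1.47-fold for Mcm3 (log2 -0.56 ± 0.11, SE; n = 3 old and 5 young arrays) to 1.86-fold for Mcm7 (-0.90 ± 0.12). Mcm2, Mcm3 and Mcm4 were not called after quantile normalization, nor Mcm2 and Mcm4 without old HSC replicate 1 or 2. With the interquartile range of each array as a covariate, Mcm2 to Mcm5 were not called. Of 29 genes of oxidative phosphorylation 22 fell, such as Sdhb, a subunit of succinate dehydrogenase, by 2.07-fold (-1.05 ± 0.19). Of 28 genes that earlier studies reported as higher in old HSC 12 rose (camera adjusted p = 8.63e-12; adjusted p = 0.290 with an estimated correlation), among them the cation channel gene Trpc1, 2.84-fold (1.50 ± 0.18), and the phospholipid scramblase family member Plscr2, 2.54-fold (1.35 ± 0.24). In total 2213 of 19296 genes were called at an adjusted p under 0.05, 434 higher and 1779 lower (80.4% lower) in old HSC, and 123 of them differed by more than 2-fold. At an unadjusted p under 0.05 there were 6054 genes, against 964.8 from chance alone.

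Among called genes whose old and young values did not overlap, the largest increases in old HSC were in Gpr183, an oxysterol receptor that guides B cell migration, which rose 3.42-fold (log2 1.77 ± 0.18; adjusted p = 1.01e-04), Tnfrsf26, 3.02-fold, Trpc1, Clca3a1, 2.73-fold, Clec9a, a receptor of dendritic cells, 2.73-fold, Zg16, 2.57-fold, Plscr2 and Fhdc1, 2.49-fold. The largest decreases among them were in the myosin light chain gene Myl10, 5.73-fold (log2 -2.52 ± 0.32; adjusted p = 3.56e-04), the glutathione transferase gene Mgst1, 4.60-fold, the small nucleolar RNA gene Rnu3a, 3.34-fold, Plac8, 3.32-fold, the galectin gene Lgals1, 3.30-fold, Lipo3, 3.22-fold, the lysosomal protease gene Ctss, 2.96-fold, and 9030619P08Rik, 2.90-fold. For 3 of these 16 genes, Tnfrsf26, Mgst1 and Rnu3a, young HSC replicate 4 lay nearer to the old HSC mean than to the other young arrays.

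Among sort markers in HSC, Cd34 fell 2.04-fold with age (log2 -1.03 ± 0.14) and Flt3, the gene of the Flk2 marker excluded by the gate, fell 1.62-fold (-0.69 ± 0.12). Kit, Cd48, Slamf1 (CD150), Fcgr3 and Fcgr2b were not called, with log2 differences of 0.03, -0.31, 0.24, 0.12 and -0.06. Cdkn2a, the gene of the senescence marker p16, was not called (0.10 ± 0.11, adjusted p = 0.551).

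Of 31 measured genes of the replication fork and DNA synthesis, 21 fell in old HSC and 0 rose (23 adjusted over the list alone), with a median of -0.58 log2. Rpa3, of the single-strand binding complex, fell 2.20-fold, the clamp loader genes Rfc2 and Rfc4 fell 2.07-fold and 1.82-fold, and the primase gene Prim1 fell 1.87-fold. Of 16 genes of origin licensing and the MCM helicase, 9 fell (11 adjusted over the list alone; median -0.45), including the licensing inhibitor gene Gmnn, 2.20-fold. Of 19 genes of the ATR and replication stress checkpoint, 9 fell (10 adjusted over the list alone; median -0.40), among them the fork protection gene Tipin, 1.87-fold, and the kinase gene Chek1, 1.70-fold. By camera the adjusted p was 8.95e-15 for the fork list, 7.33e-09 for licensing and 3.47e-05 for the checkpoint; it was 0.283, 0.283 and 0.290 with an estimated correlation. The mean of the fork list was 8.71 ± 0.03 log2 in old HSC (SD, n = 3) and 9.25 ± 0.13 in young HSC (n = 5), and that of the licensing list 8.37 ± 0.06 and 8.89 ± 0.09, with no overlap in either list.

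Of 24 genes of homologous recombination and the Fanconi anaemia pathway 2 fell, Nbn by 1.44-fold and Blm by 1.40-fold (3 adjusted over the list alone; median -0.14), and of 10 end-joining genes 1 fell, the Ku80 gene Xrcc5, by 2.04-fold (2 adjusted over the list alone; median -0.19). The camera adjusted p was 0.0654 and 0.192, but recombination was called lower without old HSC replicate 1 (0.0343) or 2 (0.0223) or young HSC replicate 3 (0.0396) or 5 (0.0232). Of 21 p53 target and senescence genes 1 fell, Glb1, by 1.48-fold (0 adjusted over the list alone; median -0.07, adjusted p = 0.858). Of 25 mitotic genes 8 fell (14 adjusted over the list alone; median -0.37, adjusted p = 3.47e-05), such as the mitotic kinase gene Cdk1, 1.70-fold, and the cyclin gene Ccnb2, 1.63-fold; the adjusted p was 0.410 with an estimated correlation. Of 21 genes of G1 cyclins, CDK inhibitors and E2F factors 6 fell and 1 rose, the same numbers adjusted over the list alone (median -0.16, adjusted p = 0.0254, and 0.410 with an estimated correlation). The G1/S genes Ccne2 and Cdk2 fell 1.97-fold and 1.77-fold, and Cdk6 rose 1.45-fold. The G1 list lost its call without old HSC replicate 2 (adjusted p = 0.0766) and without young HSC replicate 1 (0.0507).

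In metabolism, 22 of 29 oxidative phosphorylation genes fell in old HSC (26 adjusted over the list alone; median -0.60). Besides Sdhb these included the complex I gene Ndufb3, 1.87-fold, the ATP synthase gene Atp5o, 1.80-fold, and the complex III gene Uqcrc1, 1.76-fold. The camera adjusted p was 4.11e-13, and 0.383 with an estimated correlation. The list mean was 9.98 ± 0.13 log2 in old HSC and 10.55 ± 0.28 in young HSC, and young HSC replicate 4, at 10.09, lay below old HSC replicate 3, at 10.14. Of 16 glycolysis genes 6 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.36), with Aldoc and Pfkm lower by 1.94-fold and 1.72-fold. Of 18 antioxidant and metallothionein genes 7 fell (9 fell and 1 rose adjusted over the list alone; median -0.34), such as the peroxiredoxin gene Prdx4, 1.95-fold. Of 15 autophagy and lysosome genes 3 fell (6 adjusted over the list alone; median -0.28), such as the cathepsin gene Ctsd, 1.68-fold. Ribosome biogenesis genes fell in 10 of 32 cases (13 adjusted over the list alone; median -0.28), such as Polr1d, a subunit of RNA polymerases I and III, 1.91-fold, and Nop10, 1.87-fold. Of 34 cytosolic ribosomal protein genes 4 fell (4 adjusted over the list alone), such as Rpl14, 1.83-fold, and their median was -0.17 but 0.01 after quantile normalization. The camera adjusted p of these 5 lists was 2.08e-04, 0.0110, 0.00346, 2.42e-06 and 8.07e-04; with an estimated correlation it was 0.410 for the first 4 and 0.528 for ribosomal proteins.

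Of 28 genes from the literature that are higher in old HSC, 12 rose and 0 fell (18 adjusted over the list alone; median 0.55, adjusted p = 8.63e-12, and 0.290 with an estimated correlation). Besides Trpc1 and Plscr2 these included Cavin2, 2.48-fold, a gene of membrane caveolae, and Klhl4, 2.36-fold. The mean of the literature list was 8.76 ± 0.25 log2 in old HSC (SD, n = 3) and 8.10 ± 0.38 in young HSC (n = 5), and the groups overlapped. Young HSC replicate 1, at 8.490, lay above old HSC replicate 2, at 8.481, and young HSC replicate 4 was lowest, at 7.48. Chromatin modifiers fell in 6 of 28 cases (6 adjusted over the list alone; median -0.21, adjusted p = 8.45e-05, and 0.290 with an estimated correlation), among them the Polycomb methyltransferase gene Ezh2, 1.48-fold, and Satb1, 1.89-fold. Of 23 interferon response genes 4 fell (4 adjusted over the list alone; median -0.20, adjusted p = 0.0120, and 0.383 with an estimated correlation), such as Rsad2, 1.52-fold, and Dhx58, 1.51-fold. Of 23 unfolded protein response and heat shock genes 1 fell, Hsph1, by 1.59-fold (4 adjusted over the list alone; median -0.20, adjusted p = 0.00714, and 0.522 with an estimated correlation). Without old HSC replicate 2 the interferon list (adjusted p = 0.116) and the unfolded protein response list (0.352) were not called.

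Lists of cell identity were not called in HSC with age, apart from markers of mast cells and of T and NK cells. Of 23 HSC identity genes 0 changed (median -0.04), as did 0 of 23 NF-kB genes (median -0.07), both by limma and adjusted over the list alone. Of 18 megakaryocyte and platelet genes Itgb3 and Clec1b rose, 2.17-fold and 1.74-fold, and 2 fell, among them Gp5, 1.79-fold; their median was -0.15 while the test pointed up. Of 22 lymphoid genes 3 fell, among them Ltb, 1.92-fold, Satb1 and Flt3, and 2 rose, among them Dntt, 1.37-fold (3 and 3 adjusted over the list alone). Of 23 granulocyte and monocyte genes 3 fell, Lyz2, Csf2rb and Spi1, by 1.87-fold, 1.56-fold and 1.50-fold (4 fell and 1 rose adjusted over the list alone). In the lymphoid, granulocyte and mature neutrophil lists the medians were 0.09, 0.09 and 0.09 while the means were -0.03, -0.03 and -0.09. Of 25 immediate early genes 3 rose, such as Egr2, 1.71-fold, and 1 fell, Dusp2, 1.63-fold (median -0.11; 4 and 2 adjusted over the list alone). Markers of other cell types had medians of 0.18 for erythroid cells (Slc4a1 rose 1.31-fold), 0.16 for B cells (Pou2af1 rose 1.42-fold), 0.08 for macrophages and 0.19 for endothelium (Emcn fell 2.27-fold; the list was called higher without old HSC replicate 1, adjusted p = 0.0466), and Anxa1, on the neutrophil list, fell 1.70-fold. The mast cell list was called higher (0 of 11 genes called; median 0.22, adjusted p = 0.0365) but not without old HSC replicate 1 (0.111) or young HSC replicate 2 (0.0540), and the T and NK cell list (Klrb1c rose 2.22-fold and Nkg7 fell 1.52-fold; median 0.14, adjusted p = 0.0187) not without old HSC replicate 2 (0.0684). With an estimated correlation the adjusted p of both was 0.410.

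Among all 31 lists, 17 were called in HSC with age, 14 lower and 3 higher; 0 were called with an estimated correlation and 11 by fry. Against random lists matched on mean expression, the medians of fork, oxidative phosphorylation, licensing, checkpoint and mitotic genes lay at percentiles 0, 0, 0.38, 0.81 and 1.71, and the literature list at 100; after quantile normalization the checkpoint list lay at 12.2. HSC identity, a list that was not called, lay at 98.6. Antioxidants (3.28), interferon (4.84), glycolysis (6.81), ribosome biogenesis (26.3), autophagy (30.8), chromatin modifiers (54.4), G1 genes (55.3), the unfolded protein response (63.05), T and NK cells (70.5), ribosomal proteins (79.9) and mast cells (88.8) lay within the central 95% of such lists. After quantile normalization HSC identity (93.5) lay within it too, while glycolysis (1.84) and recombination (0.65, against 6.27 before) lay below it. The median difference across all genes ran with brightness, from 0.17 log2 in group 3 to -0.30 in group 9 of 10 equal groups of genes ordered by mean expression; after quantile normalization these were 0.03 and -0.03. After quantile normalization 1310 genes were called, 532 higher and 778 lower (59.4% lower), and 5 lists: licensing (median -0.30), fork (-0.38), checkpoint (-0.11), oxidative phosphorylation (-0.32) and the literature list (0.74). The count moved with single arrays: without old HSC replicates 1, 2 and 3 it was 427, 345 and 3222, and without young HSC replicates 1 to 5 it was 1485, 907, 913, 5312 and 1360. Of the 75 called genes named here, 56 were called after quantile normalization, 51 without old HSC replicate 1, 48 without old HSC replicate 2 and all without young HSC replicate 4. With a fit that adjusted for each array's interquartile range 105 genes were called, 22 of the 75 among them, and without replicate 4 of both young groups 6183 were called. Over the 5312 genes called without it, young HSC replicate 4 lay at a median of 0.215 of the way from the old HSC mean to the mean of the other young HSC arrays, where the other 4 young arrays, left out in turn, lay at 0.874 to 1.21. Old HSC replicate 3, over the 3222 genes called without it, lay at 0.435 of the way from the young HSC mean to the other old arrays, with 58.1% of these genes nearer the young mean, and old HSC replicates 1 and 2 lay at 0.914 and 0.851. On the same scale young HSC replicate 4 lay at 0.905 for the licensing list, 0.765 for fork, 1.07 for checkpoint, 1.96 for mitotic, 0.986 for interferon and 0.832 for chromatin genes, and beyond the other young arrays, at 2.57, for the literature list. It lay nearer the old mean for oxidative phosphorylation (0.151), G1 genes (0.398), ribosome biogenesis (0.442), autophagy (0.00719), glycolysis (-0.0769), antioxidants (-0.727), ribosomal proteins (-0.0898), the unfolded protein response (-0.0443) and mast cells (0.142), and at 0.819 for T and NK cells.

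**Figure D2:**
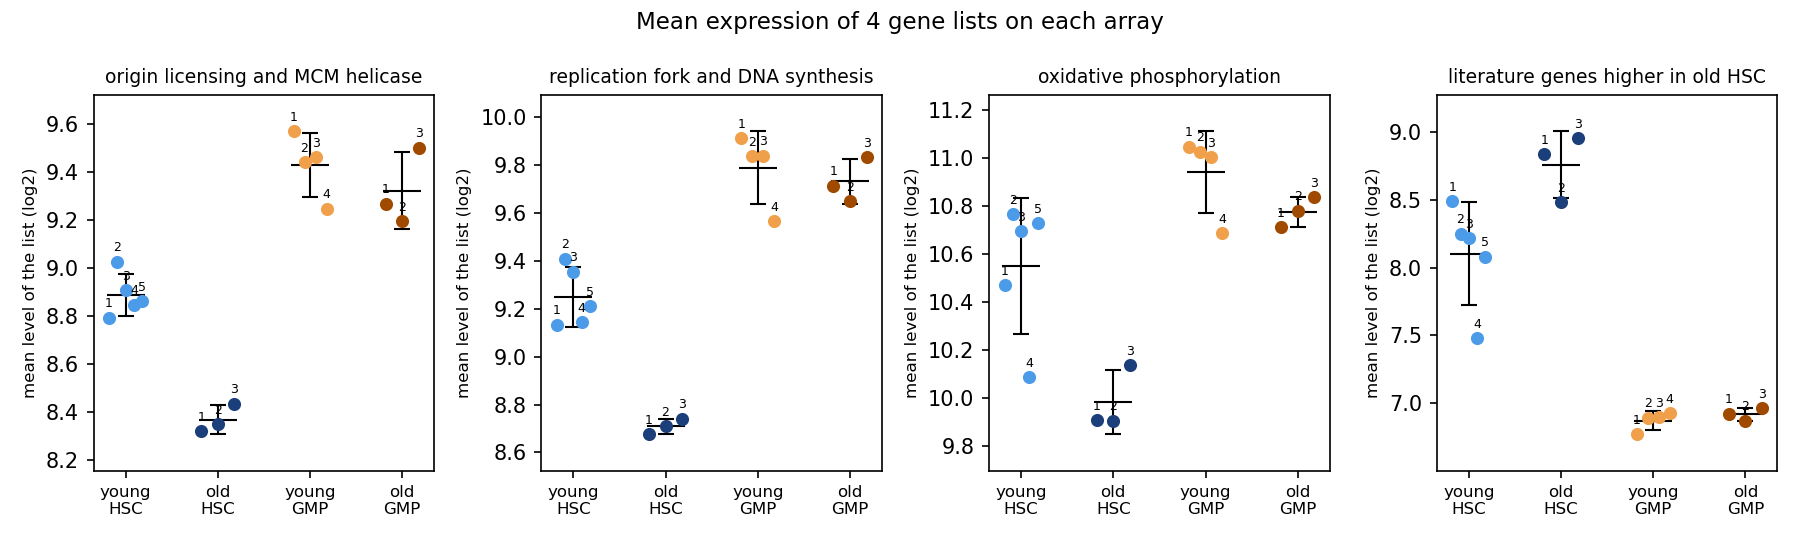
Mean level (log2, vertical axis) of 4 fixed gene lists on each array, 1 point per array with its replicate number, by group, with bars for the group mean and SD. The fork list averaged 8.71 in old and 9.25 in young HSC without overlap, while young HSC replicate 4 lay among the old arrays for oxidative phosphorylation (10.09).

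The second comparison asked whether GMP differ with age in the same way. No single gene passed the test in GMP: limma called 0 of 19296 genes, with a smallest adjusted p of 0.294, and 870 genes had an unadjusted p under 0.05, against 964.8 from chance alone. The gene nearest the threshold was Flt3, 1.66-fold higher in old GMP (log2 0.73 ± 0.13, SE; n = 3 old and 4 young arrays). Fcer1a, a mast cell receptor gene, was 2.40-fold higher (1.26 ± 0.29, adjusted p = 0.575), the lymphoid gene Dntt 1.51-fold higher (0.59 ± 0.15, adjusted p = 0.628), and the chemokine gene Cxcl2 2.48-fold lower (-1.31 ± 0.29, adjusted p = 0.575). The 95% interval of a gene's difference extended by a median of 0.298 log2 to either side. Mcm2 to Mcm7 differed by -0.28 to 0.11 log2 and were not called.

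Of the 31 lists, camera called 5 in GMP with age, and 0 were called with an estimated correlation or by fry. Oxidative phosphorylation (median -0.20, adjusted p = 5.67e-04) and immediate early genes (-0.22, adjusted p = 1.98e-04) were lower, as were mature neutrophil markers (-0.14, adjusted p = 0.0441). Mitotic genes (0.16, adjusted p = 0.00143) and lymphoid genes (0.07, adjusted p = 0.0156) were higher. With an estimated correlation the adjusted p was 0.871 for the first 4 and 0.185 for the lymphoid list. Over all genes 0 members of these lists were called, and adjusted over the list alone 1 fell in the immediate early and 1 in the neutrophil list and 2 rose in the lymphoid list, Flt3 and Dntt. The fork and licensing lists had medians of -0.08 and -0.10 and were not called (adjusted p = 0.312 and 0.0877). With array weights 832 genes were called, and without replicate 4 of both young groups 188. Without young GMP replicate 4 alone, 12 genes and 13 lists were called, fork (adjusted p = 0.00372) and licensing (0.00420) among them. Without old GMP replicate 1 only 1 list was called, mitotic genes, a list that was not called without old GMP replicate 2 (0.562). The neutrophil list was not called without old GMP replicate 1 (0.112) or 2 (0.158) or young GMP replicate 2 (0.381) or 3 (0.0684). Without old GMP replicate 3, fork (0.0320) and licensing (6.12e-04) were called lower.

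The difference between the age effects of HSC and GMP was tested directly and was called for 18 genes, 5 with a more positive and 13 with a more negative change in HSC. Flt3 showed the smallest adjusted p (0.00280): it was 1.62-fold lower in old than young HSC and 1.66-fold higher in old than young GMP, a difference of -1.43 ± 0.18 log2 (SE). Mcm6 was called as well (-0.85 ± 0.16, adjusted p = 0.0461), while Mcm2, Mcm3, Mcm4, Mcm5 and Mcm7 were not, at -0.58, -0.67, -0.43, -0.58 and -0.62. Cd34 missed the threshold (-1.01 ± 0.21, adjusted p = 0.0870). Rnase6 (-1.88), Plac8 (-1.76), Tspan6 (-1.72), Lgals1 (-1.72), Ctss (-1.53) and the costimulatory receptor gene Cd86 (-1.51) had the largest negative differences. Gpr183 (1.63), Trpc1 (1.59), Zg16 (1.51), Tmem47 (1.30) and Tdrd9 (1.17) had positive ones. Without the dimmest 40% of genes 12 genes were called, 1 with a more positive and 11 with a more negative change in HSC. Of the positive genes only Gpr183 lay outside that dimmest 40%. Named although outside the rule were the remaining 5 called genes, Itm2a (-1.33), Plxdc2 (-1.18), Cd37 (-0.97), Ebi3 (-0.85) and the ribonucleotide reductase gene Rrm1 (-0.81). With the replicate number as a block 22 genes were called, 10 of the 18 among them, and Cd86, Ebi3, Gpr183, Itm2a, Mcm6, Rrm1, Trpc1 and Tspan6 were not (adjusted p = 0.0508 to 0.0519).

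**Figure D3:**
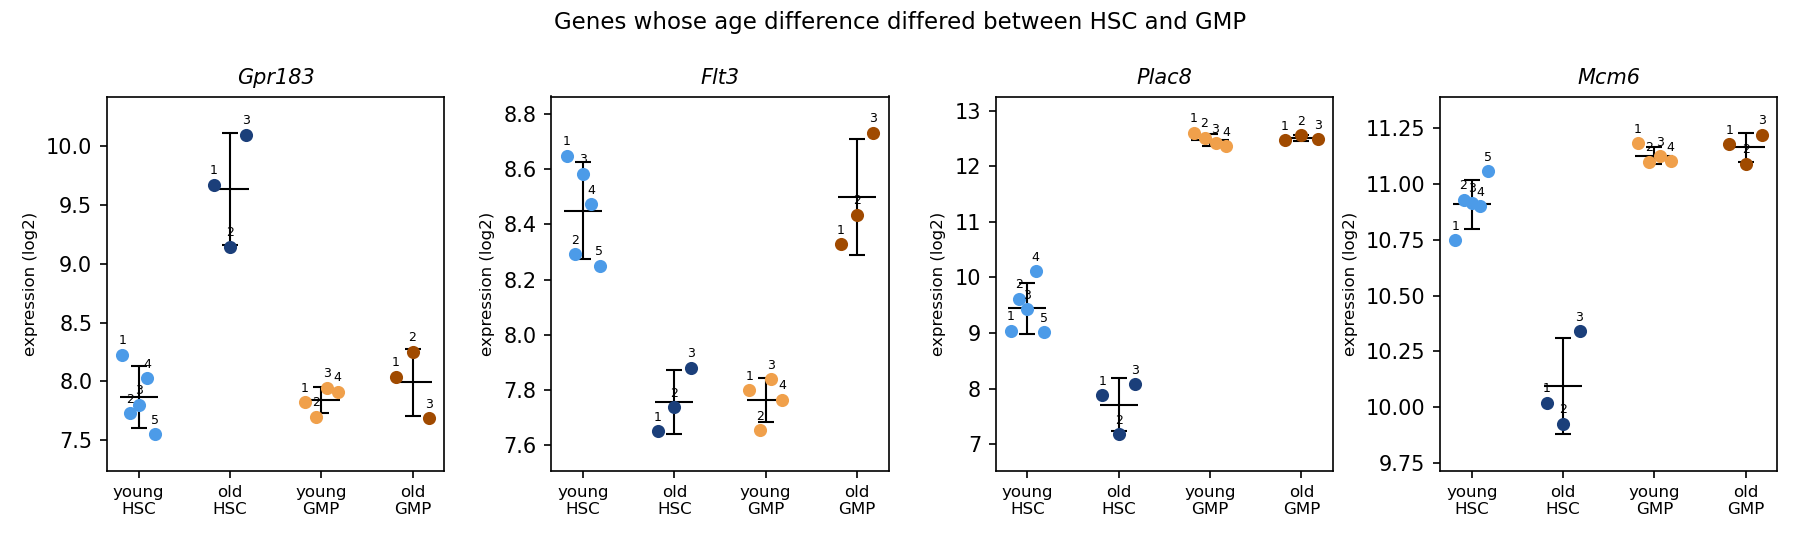
Expression (log2, vertical axis) of Gpr183, Flt3, Plac8 and Mcm6 on each array, 1 point per array with its replicate number, by group, with bars for the group mean and SD. Gpr183 rose 3.42-fold and Flt3 fell 1.62-fold with age in HSC, while in GMP Flt3 was 1.66-fold higher in old mice without being called.

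Of the lists, 12 differed in their age shift between HSC and GMP by camera, 11 with a more negative shift in HSC. The fork list had a median difference of -0.53 (18 genes adjusted over the list alone, 1 over all genes; adjusted p = 1.46e-14), mitotic genes -0.52 (9.16e-10), licensing -0.44 (2.08e-07), oxidative phosphorylation -0.40 (1.63e-08), glycolysis -0.39 (5.51e-06), the ATR checkpoint -0.36 (1.06e-05) and ribosome biogenesis -0.32 (2.65e-08). Autophagy (-0.23, 0.0243), chromatin modifiers (-0.21, 4.47e-05), G1 genes (-0.18, 0.0499) and ribosomal proteins (-0.12 but 0.02 after quantile normalization, 0.0402) followed, and the literature list was more positive in HSC (0.56, 1.21e-10). With an estimated correlation 0 lists were called (smallest adjusted p = 0.245), and fry called 4: fork, licensing, checkpoint and chromatin modifiers. G1 genes lost their call without old GMP replicate 2 or 3, old HSC replicate 2, young GMP replicate 3 or 4, or young HSC replicate 1, 2 or 3 (adjusted p = 0.0535 to 0.166). Ribosomal proteins lost it without old GMP replicate 2, old HSC replicate 1 or 2, young GMP replicate 4, or young HSC replicate 2 or 5 (0.0638 to 0.358), and autophagy without old HSC replicate 2 (0.108) or young GMP replicate 4 (0.0837). Other lists gained a call, such as immediate early genes without old HSC replicate 1 (0.00641) and the unfolded protein response without old HSC replicate 3 (0.00145). Antioxidant, interferon, HSC identity, neutrophil, and T and NK cell genes also gained one without at least 1 array. Without single arrays the gene count was 4, 1 and 2 (old GMP replicates 1 to 3), 1, 12 and 21 (old HSC replicates 1 to 3), 8, 5, 1 and 4 (young GMP replicates 1 to 4) and 17, 3, 1, 192 and 3 (young HSC replicates 1 to 5). It was 145 without replicate 4 of both young groups and 5 with the interquartile range as a covariate.

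HSC and GMP differed in the genes that define the sorted populations. In young mice the stem cell regulator gene Mecom was 20.9-fold higher in HSC (log2 4.39 ± 0.13, SE; n = 5 HSC and 4 GMP arrays) and Mmrn1 30.0-fold higher (4.91 ± 0.20), while the neutrophil granule genes Ctsg and Mpo were 80.1-fold and 79.7-fold lower (-6.32 ± 0.12 and -6.32 ± 0.15). Gimap6, Aldh1a1, Gm4951 and Plxdc2 were also 14.6-fold to 19.9-fold higher in HSC, and Ms4a3, Atp8b4, Clec12a and Hp 42.0-fold to 60.9-fold lower. On the young HSC arrays Atp8b4 lay at 6.09 log2 or lower, below the arrays' lower quartile of 6.10 to 6.33, so its fold is not exact. Among the sort markers, Slamf1 was 10.1-fold higher in HSC and Kit, positive in both gates, 2.08-fold higher, and Cd48, Fcgr3, Fcgr2b and Cd34 were lower by 18.3-fold, 14.4-fold, 3.49-fold and 1.49-fold. Flt3, the gene of the Flk2 marker that the HSC gate excludes, was 1.61-fold higher in young HSC than in young GMP and 1.67-fold lower in old HSC than in old GMP. In young mice 4741 genes were called, 2633 higher and 2108 lower in HSC, and in old mice 4292, 1785 higher and 2507 lower, of which 2974 were called in both with the same sign. After subtraction of each array's median the old comparison split into 1364 higher and 2963 lower, and after quantile normalization into 2214 and 2361. In old mice the 6 largest decreases were the same genes, while Cysltr2, 19.7-fold, Clca3a1, 18.5-fold, and Klhl4, 17.3-fold, took the place of Gimap6, Aldh1a1 and Plxdc2 among the increases.

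In young mice 22 of 23 HSC identity genes were higher in HSC (22 adjusted over the list alone; median 2.10), 21 of 23 granulocyte and monocyte genes lower (22; -2.18), 14 of 18 megakaryocyte genes higher and 1 lower (14 and 1; 0.85), such as Pf4, 5.68-fold, 16 of 23 interferon genes higher and 2 lower (17 and 2; 0.70), such as Oasl2, 4.97-fold, and 8 of 11 mast cell and basophil genes lower (8; -1.36), such as Mcpt8, 21.9-fold. These 5 lists kept their call with an estimated correlation (adjusted p = 0.00864, 0.00197, 0.0267, 0.0149 and 0.0149). A further 11 lists were called by camera but not with an estimated correlation (adjusted p = 0.0655 to 0.593). All 25 mitotic genes were lower in HSC (25 adjusted over the list alone; median -0.93), such as Bub1, 3.24-fold, as were 22 of 31 fork genes, such as Rrm2, 3.58-fold, 12 of 16 licensing genes, 10 of 19 checkpoint genes, 15 of 24 recombination genes, such as Fancd2, 2.57-fold, 13 of 29 oxidative phosphorylation and 10 of 32 ribosome biogenesis genes. Immediate early genes were higher in 17 of 25 cases, such as Nr4a1, 6.76-fold, and lower in 1, and literature genes of old HSC were higher in 22 of 28 and lower in 2. Mature neutrophil markers were lower in 8 of 16 cases, such as S100a8, 10.8-fold, and higher in 1. Unfolded protein response genes were lower in 8 of 23 cases, such as Edem1, 2.66-fold, and higher in 3, and that list was not called without young HSC replicate 4 (adjusted p = 0.0587).

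Across all 19296 genes the age differences in HSC and in GMP had a Pearson correlation of 0.370 and a Spearman correlation of 0.299; genes are not independent replicates, so no p is given. The correlation was 0.240 without old GMP replicate 1, 0.213 without young GMP replicate 1 and 0.548 without replicate 4 of both young groups. Other splits of the ages that moved same-numbered HSC and GMP arrays together gave correlations of -0.136 to 0.681, with a median of 0.202.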

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

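The tests of where young HSC replicate 4 lies and of the Y-linked genes were chosen only after the result was seen, as were the fits with Xist or the interquartile range as a covariate, those without the replicate 4 arrays, and the splits that keep or part all same-numbered pairs; the other tests were chosen before.

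Xist was present on young arrays although every sample was labelled male, and young HSC replicate 1, at 4.72 log2, lay far below the other 4 young HSC arrays, which lay between 10.02 and 11.51. Cells of female mice in the young samples are a candidate explanation: from the array with the lowest to the array with the highest Xist, the mean of 3 Y-linked genes changed by -3.86 log2 in young HSC and by -3.41 in young GMP. Xist was also alike in HSC and GMP arrays of the same number, with summed differences of 3.08 log2, and 2 of 24 ways to pair the arrays gave a sum as small. Young HSC replicate 2 carried both signals, with Xist at 11.16 and a Y-linked mean of 7.12, against 4.94 on replicate 4. The labels do not say whether mice were pooled, and since they give 1 sex no biological explanation was tested.

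More genes were lower than higher in old HSC, 80.4% of the 2213 called. The 2 HSC arrays that stand apart, old replicate 2 and young replicate 4, are argued against as the whole source, since 74.96% were lower without them and young GMP replicate 4, although 61.2% were lower without the replicate 4 arrays alone. The narrower spread of values on the old HSC arrays may account for some or all of the excess, since 59.4% were lower after quantile normalization, which gives each array the same spread. With the interquartile range of each array as a covariate no excess remained, with 54 higher and 51 lower, although only 105 genes were called. A difference between arrays that young replicate 4 shares with the old arrays and age cannot be told apart here: from the old HSC mean to the other young arrays, that array lay at 0.226 of the way over genes called lower without it and at 0.197 over genes called higher, which does not bear on the direction. The share was also 56.8% with Xist as a covariate (1542 higher, 2029 lower) and 54.2% with array weights (4108, 4858), where calls rose in both directions from 434 and 1779, and age itself stays open as untested.

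The DNA replication and oxidative phosphorylation lists were called lower in old HSC by camera, but not with an estimated correlation (adjusted p = 0.283 for licensing and fork and 0.383 for oxidative phosphorylation). A weaker signal of all bright genes would lower equally bright random lists alike, but the 3 list medians lay at or below percentile 0.38 of such lists. The random genes were drawn singly, without the correlation between genes of a real list. The percentiles may therefore overstate how rare such medians are, and they do not settle whether brightness is the whole source. The medians kept 54.2% to 66.7% of their size after quantile normalization. Oxidative phosphorylation went from -0.60 to -0.24 with the interquartile range as a covariate. With Xist as a covariate each median kept at least 98.9% of its size. This fit cannot decide whether female mice among the young samples contribute, because log2 Xist did not follow the Y-linked signal. Young HSC replicate 3 had Xist at 10.02 and a Y-linked mean of 8.47, and young HSC replicate 4 had 11.51 and 4.94. Female mice therefore stay open as a source. For oxidative phosphorylation, a difference between arrays shared by young replicate 4 and the old arrays is a candidate explanation, since young HSC replicate 4 lay at 0.151 of the way from the old to the other young HSC arrays. That position rests on 1 array. For the 2 replication lists the same array lay at 0.765 (fork) and 0.905 (licensing), within the range of the other young HSC arrays. Left out in turn, those lay from 0.743 (replicate 1) to 1.40 (replicate 2) for fork and from 0.782 to 1.36 for licensing. These positions give no sign of such a shared difference in the replication lists. Because they too rest on 1 array, this explanation and age cannot be told apart there. Age stays open as untested for all 3 lists.

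Other splits of the arrays were set against each count. For age in HSC chance could not be excluded, since 3 of the 56 splits called as many genes: the real one 2213, the highest other 5275. That highest split exchanged old HSC replicate 3 with young HSC replicate 4 and points to a structure of the samples other than the labelled ages. For age in GMP the splits decide nothing, since with 0 genes called all 35 of 35 splits give as many (highest other 37). For HSC against GMP in young mice 1 of 100 drawn splits gave as many genes, the real one (4741, highest other 4344, a near mirror of the real split that left only young HSC replicate 4 in place), which excludes chance where the arrays are taken as unpaired. Of these splits 85 left a same-numbered pair together. Among the 16 splits that part all 4 pairs, 1 gave as many (4741, highest other 2678), and 16 splits are too few for a share under 0.05. For HSC against GMP in old mice 1 of 10 splits gave as many genes (4292, highest other 0), and 10 splits are too few for a share under 0.05. For the difference between both age effects 3 of 100 drawn splits gave as many as the real 18 genes, and the highest other called 1688, which points to a structure of the samples. Those splits move HSC and GMP arrays separately and so break the same-numbered pairs. Among the 35 splits that move HSC and GMP arrays of a number together, 1 gave as many, the real one, and the highest other called 4. This excludes chance only where old HSC and old GMP arrays of a number are taken as pairs. Their deviations correlated by 0.05 for number 1, and number 2 correlated as well with another number (0.23). Only number 3 stood apart (0.42). Because that pairing was not shown for the old arrays, these splits cannot decide whether chance accounts for the 18 genes. For the correlation of age effects chance could not be excluded (11 of 35 splits; 0.370, highest other 0.681).

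A single array lay far from the rest of its group in 25 of 300 groups of values tested. For a single test chance gives about 1 in 20. These groups of values come from the same young arrays and are not independent, so the count does not measure an excess over chance. Young GMP replicate 4 was that array in 12 cases and young HSC replicate 4 in 10. Young GMP replicate 4 was lowest for Mgst1 (8.90 log2), Cavin2 (5.88), Csf2rb (8.35), Anxa1 (9.71), Nkg7 (11.04), Atp8b4 (11.27), Clec12a (10.70) and Rrm2 (10.15) and highest for Pou2af1 (7.01). In list means it was lowest for ribosomal proteins (12.00), oxidative phosphorylation (10.69) and the granulocyte programme (9.83). Young HSC replicate 4 was lowest for Ndufb3 (7.78), Klhl4 (7.95), Cd37 (8.43) and Aldh1a1 (9.60) and highest for Atp8b4 (6.09). In list means it was highest for homologous recombination (8.06) and lowest for autophagy (8.91), antioxidants (8.96), megakaryocyte genes (7.88) and the unfolded protein response (10.07). Young GMP replicate 1 was highest for Cd48 (10.83), and young HSC replicate 3 for the granulocyte programme (7.37).

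The age effect differed between HSC and GMP, by the test of the difference itself, for 18 genes. Lower in HSC than in GMP (log2) were Cd37 (-0.97), Cd86 (-1.51), Ctss (-1.53), Ebi3 (-0.85), Flt3 (-1.43), Itm2a (-1.33), Lgals1 (-1.72), Mcm6 (-0.85), Plac8 (-1.76), Plxdc2 (-1.18), Rnase6 (-1.88), Rrm1 (-0.81) and Tspan6 (-1.72). Higher were Gpr183 (1.63), Tdrd9 (1.17), Tmem47 (1.30), Trpc1 (1.59) and Zg16 (1.51). By camera the age effect differed for 12 lists, and by fry for 4. The camera lists, with their medians, were licensing (-0.44), fork (-0.53), ATR checkpoint (-0.36), mitotic genes (-0.52), G1 genes (-0.18), ribosome biogenesis (-0.32), ribosomal proteins (-0.12), oxidative phosphorylation (-0.40), glycolysis (-0.39), autophagy (-0.23), chromatin modifiers (-0.21) and literature genes (0.56). The gene count ranged from 1 without old GMP replicate 2, old HSC replicate 1, young GMP replicate 3 or young HSC replicate 3 to 192 without young HSC replicate 4, and 0 lists were called with an estimated correlation.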

How the results depend on the processing

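The covariate fits and those without the replicate 4 arrays were chosen only after the result was seen; the other alternatives were chosen before. HSC against GMP was the most stable result: in young mice 3919 to 5494 genes were called when leaving out each array in turn and 6121 with the replicate block, against 4741, and in old mice 3272 to 4220 and 5392, against 4292, with 7494 under array weights. Of the 31 lists in young mice, 15 to 16 were called without single arrays and 5 with an estimated correlation.

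The count of genes changed with age in HSC, 2213, was 1310 after quantile normalization (940 called in both with the same sign), 8966 with array weights, 871 with only the groups compared, 105 with the interquartile range as a covariate (82 shared), 3571 with Xist as a covariate, 6183 without replicate 4 of both young groups and 3439 without old HSC replicate 2 as well, and 345 to 5312 without single arrays. The cause was not tested. The percent lower among these genes ranged from 65.0 to 86.7 without single arrays and was 48.6 with the interquartile range and 56.8 with Xist as a covariate, 54.2 with array weights, 59.4 after quantile normalization and 89.9 with only the groups compared. For age in GMP 0 genes became 832 with array weights, 188 without the replicate 4 arrays and 282 without old HSC replicate 2 as well, and 0 to 12 without single arrays. For the difference of age effects 18 became 2407 with array weights, 5 with the interquartile range, 145 and 121 without those arrays, and 1 to 192 without single arrays. The cause was not tested.

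With the replicate block, 5449 genes were called with age in HSC and 103 in GMP, 22 for the difference of age effects (10 of the 18 among them), and 12 lists in GMP, and the correlation of age effects was 0.530. For age within a cell type the block was the number within that cell type; young replicates 4 and 5 have numbers that no old array carries, so that this block removes them by construction. Old and young arrays of a cell type share only a number: their deviations correlated by -0.239 to 0.146. Deviations of same-numbered old HSC and old GMP arrays correlated by 0.05, 0.23 and 0.42, and number 2 correlated as well with another number (0.23). Young HSC replicate 2 likewise correlated with another number by 0.247, above its own 0.235.

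Lists called with age in HSC, 17, were 5 after quantile normalization, 9 without the dimmest 40% of genes, 7 with the interquartile range, 0 with an estimated correlation, 11 by fry and 14 to 18 without single arrays. In GMP 5 became 11 with array weights, 8 with the interquartile range, 12 without the replicate 4 arrays, 13 without old HSC replicate 2 as well, 0 with an estimated correlation, 0 by fry and 1 to 13 without single arrays. For the difference 12 became 0 with an estimated correlation, 4 by fry and 10 to 16 without single arrays. The correlation of age effects, 0.370, was 0.522 with array weights, 0.263 with the interquartile range, 0.655 with Xist, 0.548 and 0.529 without those arrays, and 0.213 to 0.529 without single arrays. The cause was not tested.

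With the interquartile range as a covariate the direction of the camera test reversed, for age in HSC, for G1 genes (median -0.031), ribosomal proteins (-0.0289), autophagy (0.00959), antioxidants (-0.193), immediate early genes (0.085, adjusted p = 0.00372) and the unfolded protein response (0.0364), and for the difference for ribosomal proteins (0.00814) and autophagy (-0.00469). Of these, immediate early genes alone were called in that fit, and the medians of G1 genes, ribosomal proteins and antioxidants for age in HSC and of autophagy for the difference kept their sign. Ribosomal proteins also reversed for the difference after quantile normalization (0.0249). Xist itself has no value in the fit with Xist as a covariate, which leaves no difference in it. Signal over background was not analysed here.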

Other observations

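These values were chosen only after the result was seen, and no planned test is reported here.

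A search was made for genes that lay, in both cell types and in the same direction, more than 1 log2 apart between the old arrays with young replicate 4 and all other young arrays. It found 3 genes, Gdpd3, Tnfrsf26 and 5830417I10Rik, and the same search with number 1, 2 or 3 in place of 4 found 1, 0 and 0. That replicate 4 lies with the old arrays on these genes follows from how they were chosen. Gdpd3, a glycerophosphodiester phosphodiesterase gene, lay between 10.59 and 11.32 log2 on the other 4 young HSC arrays and at 5.69 on replicate 4, and old HSC lay at 5.84, 8.34 and 5.63. In GMP it lay between 9.46 and 9.84 on the other 3 young arrays, at 6.76 on replicate 4, and at 6.44, 7.69 and 6.45 on the old arrays. Tnfrsf26 lay between 5.98 and 6.71 on the other 3 young GMP arrays, at 8.18 and 8.36 on the replicate 4 arrays of HSC and GMP, and between 8.22 and 8.69 on the 6 old arrays.

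The deviation of each young array from the others of its group was correlated with the age difference in the other cell type. These share no arrays but are not independent. Both subtract the mean of the other young arrays, and same-numbered young HSC and GMP arrays had correlated deviations, which can raise the correlation. For numbers 1 to 4 the correlations were 0.088, -0.110, -0.136 and 0.451 for HSC deviations against the GMP age difference, and -0.443, -0.365, -0.106 and 0.603 for GMP deviations against the HSC age difference.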
